A study of Mus musculus with 6 samples.

How the data were processed

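RNA was sequenced from endometriosis-like lesions of female C57BL/6 mice. Per the labels' protocols, the uterus of a GFP-positive donor was sutured to the peritoneal wall of a wild-type recipient, and the uterine-derived tissue was separated from recipient tissue at necropsy. Total RNA was purified with a column kit including a DNase step, and 1 µg per sample entered a TruSeq Stranded library. The labels do not say whether polyadenylated RNA was selected or ribosomal RNA was removed. There were 6 libraries, 3 from vehicle-treated and 3 from niclosamide-treated recipients. Vehicle 1 was made from RNA pooled over 4 mice, and each of the other libraries came from a single mouse.

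The deposited values are whole-number read counts per gene symbol, without normalization. Per the file headers, the authors counted reads over exons with featureCounts 1.4.6-p4 on STAR alignments, with the reverse-stranded setting, and summed the exons of each gene of the GRCm38.p3 annotation. The headers show no option to count reads that align to several places or that overlap several genes, so such reads were left out by that counter's defaults. Genes with near-identical copies (immunoglobulin segments, NK receptor genes of the Klr family, guanylate-binding proteins, Sprr2 genes) can therefore be undercounted, and their values are uncertain to that extent. The submitters' processing notes also name bcl2fastq 1.8.4, Trimmomatic 0.33, STAR 2.4.2a and edgeR 3.12.0. The counted symbols include neither the donor's GFP transgene nor the protein-coding genes of the mitochondrial genome, so donor and recipient cells are not separated in these values.

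The files hold 41786 gene symbols, of which 11820 had no count in any library. Total counts were 27797121, 34797000 and 31061717 in vehicle 1 to 3, and 31177893, 33606591 and 31050619 in niclosamide 1 to 3. A count of 3, the upper limit allowed by a count of 0, is 0.0862 to 0.108 CPM (the count of a gene relative to the library total) in these libraries, and covers counting error only. Rn18s-rs5, an 18S ribosomal RNA sequence, took 1.03%, 0.608% and 0.867% of the counts in vehicle 1 to 3 and 0.61%, 0.355% and 0.189% in niclosamide 1 to 3. No pair of libraries held the same values: Spearman correlations of log2 CPM over genes ran from 0.976 to 0.987 within the vehicle group, from 0.937 to 0.954 within the niclosamide group and from 0.949 to 0.976 between groups.

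Niclosamide was compared with vehicle by edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10 and minimum total count of 15, which left 17364 genes. Libraries were scaled by TMM, with factors of 0.987, 1.047 and 1.025 for vehicle 1 to 3 and 0.945, 0.963 and 1.037 for niclosamide 1 to 3. A quasi-likelihood model with robust dispersion estimates and the group as its only term was fitted, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are niclosamide over vehicle, and their standard errors (SE) were taken as the absolute log2 fold change over the square root of the F statistic. CPM values use the TMM-scaled library sizes. Per-library list means are averages of log2 CPM with a prior count of 2.

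Before the data were examined, 48 gene lists for pathways, cell types and RNA quality were fixed, and the 46 lists with at least 5 tested members entered limma's camera test (limma 3.58.1) with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists. For each list, the members past the threshold were also counted after adjustment over the list alone. The genes to be named were set by a rule of the same date. It took 12 fixed genes, and the 10 genes per direction with the largest fold change past the threshold whose mean log2 CPM was at least 1 and whose groups did not overlap. Should fewer than 5 genes pass in a direction, it took instead the 10 with the smallest p that met the other conditions. It also took up to 4 members per called list with the smallest p in the list's direction. Predicted genes, LOC and Rik symbols and immunoglobulin or T cell receptor segments were left out of the selection per direction. Some genes that this rule took are not reported here. Body weights from the labels were compared by a two-sided exact permutation test.

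The alternatives were other scalings (RLE, upper quartile), DESeq2 1.42.0, limma-voom without and with library quality weights, no filter and a stricter filter on low counts (CPM of at least 1 in 3 libraries), an adjusted p under 0.10, a minimum absolute log2 fold change of 1, the replicate number as a block, and leaving out each library in turn. For the lists, the correlation was also estimated per list and the fry test was run. A covariate for skeletal muscle genes was added after the data were seen.

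The procedure was tested on counts simulated for this comparison over 17364 genes, with 50 genes changed at each size. The changed genes were drawn from those with a mean above 1 CPM, so the shares recovered do not cover genes below that level. edgeR recovered 18% of the genes changed 2-fold, 74% at 4-fold, 88% at 8-fold and 92% at 16-fold, with 9 unchanged genes among 145 calls. DESeq2 recovered 42%, 88%, 100% and 100% at these sizes, with 73 unchanged genes among 238 calls. limma-voom recovered 6%, 70%, 92% and 96%, with 5 unchanged genes among 137 calls. Of 46 lists, camera called the 1 list simulated with a log2 shift of 0.8 and 0 of the 45 others, and with an estimated correlation that list had an adjusted p of 0.0399. The simulated genes varied independently of each other.

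Gene positions are 1-based in GRCm38.p3, from the first to the last exon listed in the files. Some named genes are listed on more than one contig (Ifi205, Klri2, Erdr1, Lck and Tnf), and no position is given for these.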

Results

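The experiment asked how niclosamide, an oral anthelmintic drug known to inhibit STAT3 and NF-kB signalling, affects endometriosis-like lesions in mice. Uterine tissue of 6-week-old GFP-positive donors was sutured to the peritoneal wall of 8-week-old wild-type recipients in a matched stage of the cycle. After 3 days the recipients received vehicle or niclosamide at 200 mg/kg daily for 3 weeks, and lesions were collected in diestrus. The stranded RNA-seq data comprised 3 vehicle and 3 niclosamide libraries of 27797121 to 34797000 counted reads. Vehicle 1 was a pool of RNA from 4 mice, so the vehicle group held 1 pooled value and 2 values from single animals. Body weight averaged 19.7 g ± 0.41 (SD, n = 3) with vehicle, where the first value is itself a mean over the pooled mice, and 20.2 g ± 2.0 with niclosamide. The difference of 0.48 g was smaller than the SD of the niclosamide group, though not than that of the vehicle group (two-sided exact permutation p = 1, n = 3 per group, smallest possible p 0.1). Without niclosamide 1, the heaviest animal, the difference was -0.69 g, and without niclosamide 2 it was 1.16 g.

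The genes with the smallest p among those higher in niclosamide-treated lesions included a chemokine gene and receptor genes of NK and T cells. Immunoglobulin and T cell receptor segments, some of which had larger fold changes, were left out of this selection beforehand. *Cxcl9*, which encodes an interferon-gamma-induced chemokine that attracts T cells, averaged 206 CPM ± 19.1 (SD, n = 3) with vehicle and 672 ± 211 with niclosamide, a log2 fold change of 1.71 ± 0.25 (SE). Receptor genes of NK and T cells followed. *Klrd1* (CD94) averaged 25.3 ± 3.11 CPM with vehicle and 64.2 ± 17.1 with niclosamide, *Klri2* 6.54 ± 1.35 and 15.8 ± 0.224, *Cd226* 16.6 ± 3.82 and 39.7 ± 4.28, and *Il2rb*, the shared beta chain of the IL-2 and IL-15 receptors, 67.1 ± 9.12 and 124 ± 17.8. *Fasl*, a death ligand of activated lymphocytes, had 4.97 ± 0.40 and 11.8 ± 2.43 CPM, and *AW112010* had 141 ± 13.7 and 415 ± 130. The interferon-inducible gene *Ifi205*, the transporter gene *Abcg3* and *Arhgap15* completed the set, with log2 fold changes of 0.92, 0.88 and 0.77. *Cxcl9* lies on chromosome 5 at 92321331 to 92328079, *Klrd1* on chromosome 6 at 129588092 to 129598775 and *AW112010* on chromosome 19 at 11047612 to 11050566, each measured over its annotated exons.

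Among the genes lower in niclosamide-treated lesions, *Slc24a3*, a potassium-dependent sodium/calcium exchanger gene on chromosome 2 (145167712 to 145642166), averaged 129 CPM ± 14 with vehicle and 41.6 ± 3.41 with niclosamide, a log2 fold change of -1.63 ± 0.13 (SE). *Ltbp1*, a latent TGF-beta binding protein gene on chromosome 17 (75005529 to 75392967), had 236 ± 5.60 and 104 ± 11.8 CPM. *Nkd1*, a feedback antagonist of Wnt signalling on chromosome 8 (88521344 to 88594887), had 50.0 ± 3.04 and 22.2 ± 3.31 CPM, and *Mrvi1*, a substrate of cGMP-dependent kinase in smooth muscle, had a log2 fold change of -1.34 ± 0.18 (SE). *Nipal4*, *Ccdc3*, *Erdr1*, *Dlc1* and the glutamine transporter gene *Slc38a1* had log2 fold changes of -1.99, -1.61, -1.10, -0.75 and -0.86. In each of these genes every niclosamide library lay outside the range of the vehicle libraries, which was a condition of their selection.

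**Figure D1:**
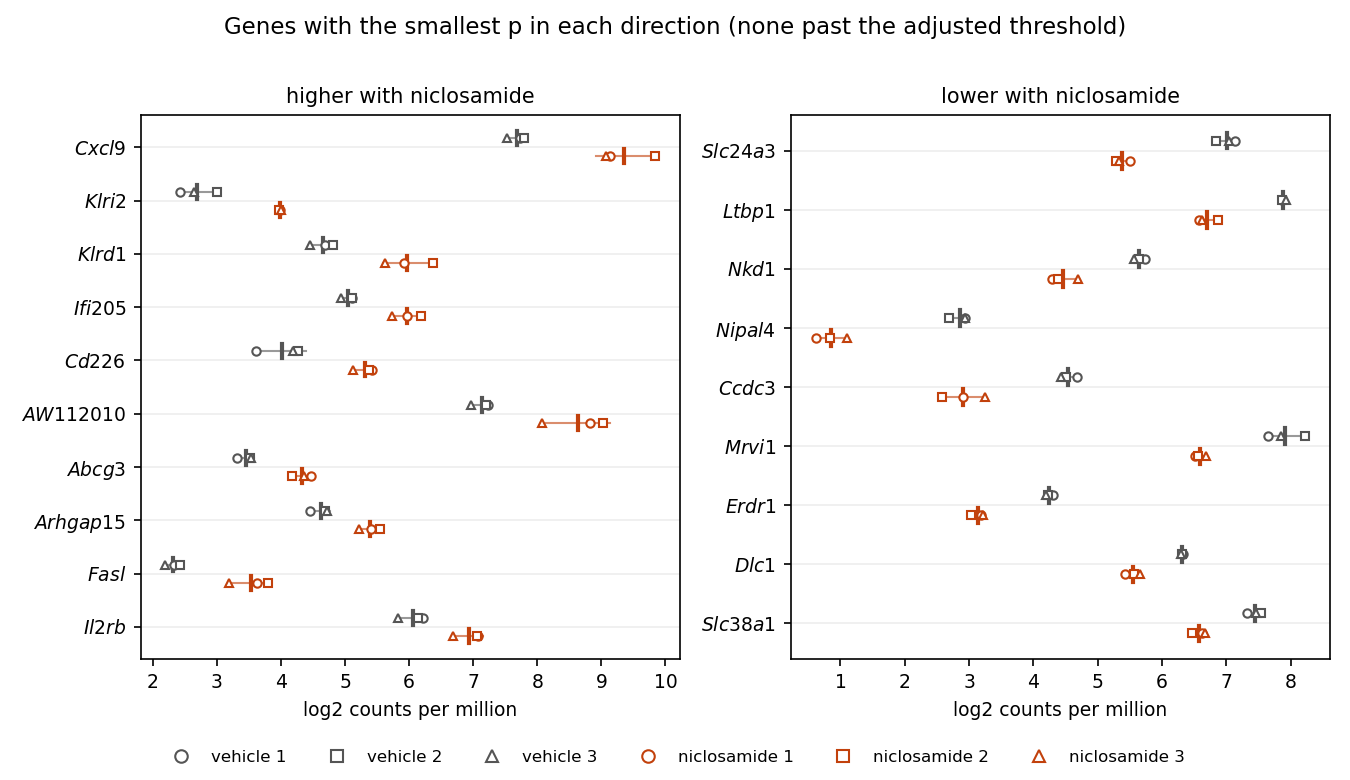
Log2 CPM of genes with the smallest p in each direction, chosen among genes whose groups do not overlap; each symbol is 1 library, the thick bar is the mean of 3 libraries and the thin line is 1 SD. Cxcl9 averages 206 CPM with vehicle and 672 with niclosamide, and Slc24a3 averages 129 and 41.6. No gene passed the adjusted threshold by edgeR, whereas DESeq2 called all genes shown.

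None of these differences passed the threshold. Of 17364 genes, 0 had a Benjamini-Hochberg adjusted p under 0.05 by edgeR's quasi-likelihood test. The lowest adjusted p was 0.174, for *Slc24a3*, and the other genes named above had adjusted p values of 0.50 to 0.52. Without a filter on low counts *Slc24a3* passed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.033), and over all alternatives its adjusted p ranged from 5.9e-15 by DESeq2 to 1 without vehicle 3. limma-voom called 0 genes, with or without library quality weights. At an unadjusted p under 0.05 there were 1202 genes, 6.92% of those tested. DESeq2's Wald test with Benjamini-Hochberg adjustment called 178 genes, 75 higher and 103 lower, among them all genes named above as higher or lower; 22 of the calls were immunoglobulin or T cell receptor segments, 20 of them higher. Of the 178, 176 were also tested by edgeR, and all 176 had an unadjusted edgeR p under 0.05. Both tests use the same counts, so this overlap is no independent support. In the simulation, 73 of 238 DESeq2 calls were unchanged genes. The groups did not overlap in 2131 tested genes (12.3%), where chance gives 10%.

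The signalling factors and receptors fixed in advance gave no call, and their transcript levels do not measure the activity of their proteins. *Stat3* had 276 CPM ± 47.0 with vehicle and 255 ± 37.2 with niclosamide (log2 fold change -0.12 ± 0.19 SE). The values were 0.06 ± 0.16 for *Nfkb1*, -0.15 ± 0.20 for *Rela*, -0.40 ± 0.28 for *Socs3*, a STAT3 target and feedback inhibitor, 0.00 ± 0.31 for *Tnf*, -0.33 ± 0.56 for *Ptgs2* and -0.18 ± 0.99 for *Il6*, which averaged only 1.35 CPM with vehicle, and 0.511 without vehicle 1. Among the steroid receptors, *Pgr* had 206 ± 92.6 and 100 ± 34.3 CPM (log2 fold change -1.04 ± 0.40), and *Esr1* 298 ± 66.0 and 200 ± 70.3 (-0.57 ± 0.31). *Esr2* had a log2 fold change of -1.61 ± 0.73, but with only 3 to 50 counts per library and at most 1.37 CPM in any of the 6 libraries. The log2 fold change was 0.57 ± 0.30 for *Vegfa* and 0.68 ± 0.37 for the proliferation marker *Mki67*. Adjusted p values of the 12 genes lay between 0.68 and 1 (edgeR quasi-likelihood, Benjamini-Hochberg). The STAT3 target list (24 genes tested) had a median log2 fold change of -0.10 (camera adjusted p = 0.50). For the NF-kB target list (28 genes) the median was 0.10, the mean of the fold changes -0.13 and the test direction upward (adjusted p = 0.94). These lists rested on single libraries: STAT3 targets were called lower without vehicle 2 (adjusted p = 0.023) or niclosamide 2 (adjusted p = 0.0092), and their direction turned without vehicle 1 (0.23), niclosamide 1 (0.92) or niclosamide 3 (0.69). NF-kB targets were called higher without niclosamide 3 (adjusted p = 0.0051) and lower without niclosamide 2 (adjusted p = 0.045), and also turned downward without vehicle 2 (0.076), vehicle 3 (0.78) or niclosamide 1 (0.71). These p values use the preset correlation of 0.01, whereas the estimated correlation was 0.43 for STAT3 and 0.68 for NF-kB targets. With estimated correlations, camera adjusted p over all libraries was 0.91 and 0.98.

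Of 46 gene lists tested by camera, 14 were called at the preset correlation, 6 higher and 8 lower. With a correlation estimated from the data 0 lists were called, the lowest adjusted p being 0.40, and fry called 0. The number called was 23 without vehicle 1 and 23 without niclosamide 2. All list calls with a library left out use the preset correlation. Estimated correlations reached 0.97 for skeletal muscle genes, and the preset p values are too small for lists whose members vary together in this way. No member of any list passed the threshold over all genes tested. The per-library list means of the 2 groups were apart in 5 of 46 lists (10.9%, where chance gives 10%), 4 of them among the called lists.

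Structural RNAs, a sign of RNA quality or library composition, also differed along the groups; they were looked at after the data were seen. Of 6 tested, 5 had a log2 fold change below 0. *Rn7sk*, the 7SK RNA, had 42.5, 17.4 and 19.1 CPM in vehicle 1 to 3 and 9.45, 2.32 and 1.03 in niclosamide 1 to 3, *Rmrp* 11.6, 5.74 and 8.45 against 3.7, 0.711 and 0.124, and *Rpph1*, the RNA of RNase P, 7.44, 2.55 and 3.55 against 1.29, 0.155 and 0.342. The groups did not overlap in these or in *Rny3*, which was below or near 1 CPM, and they overlapped in *Rn18s-rs5* (log2 fold change -1.05 ± 0.49 SE) and *Rnu73b* (0.25 ± 0.48). Their adjusted p values by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.60 to 0.97, and DESeq2 called *Rpph1* lower (adjusted p = 0.020). Symbols starting with Snord or Snora were not among the 6. Of those, DESeq2 called *Snord15b* lower (adjusted p = 0.035), at means of only 1.82 CPM with vehicle and 0.485 with niclosamide. The list of replication-dependent histones, by contrast, had means of 1.22 ± 0.19 and 1.20 ± 0.31 log2 CPM. The structural RNAs without overlap parted the libraries by group, as the means of the T and NK cell, smooth muscle, extracellular matrix and Wnt/beta-catenin lists did.

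The T and NK cell list had the smallest camera p of the 46 lists. All 24 members had a log2 fold change above 0 (median 0.78), and the list was called higher (camera adjusted p = 6.8e-24; adjusted p = 0.40 with an estimated correlation). Over all genes tested 0 members passed, and 16 rose when adjusted over the list alone. The list mean was 4.15 log2 CPM ± 0.08 (SD, n = 3) with vehicle and 5.02 ± 0.22 with niclosamide, without overlap. *Klrk1* (NKG2D) averaged 31.2 ± 7.99 and 64.7 ± 9.34 CPM, the CD3 chain gene *Cd3g* 38.5 ± 5.28 and 77.2 ± 18.2, the kinase gene *Lck* 40.4 ± 2.95 and 62.7 ± 8.75, and the T-box factor gene *Tbx21* 7.06 ± 0.618 and 13.1 ± 2.71. DESeq2 called 5 of the 24 members.

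Lists of other leukocytes were also called higher at the preset correlation, with overlapping groups. Macrophage genes had a median log2 fold change of 0.48 with 18 of 20 above 0 (adjusted p = 1.3e-07; adjusted p = 0.90 with an estimated correlation), and *Mertk*, a receptor for uptake of dying cells, averaged 33.5 ± 1.53 and 67.0 ± 33.0 CPM. Dendritic cell genes had a median of 0.53 with 15 of 16 above 0 (adjusted p = 0.00012; adjusted p = 0.70 with an estimated correlation), and *Ciita*, the regulator of MHC class II genes, averaged 60.7 ± 9.05 and 120 ± 46.3 CPM. B and plasma cell genes had a median of 0.30 with 16 of 19 above 0 (adjusted p = 1.7e-05; adjusted p = 0.91 with an estimated correlation). Their leading members were genes of antibody-secreting cells, with the joining chain gene *Igj* at 954 ± 144 and 2750 ± 1010 CPM and *Igkc* at 1530 ± 472 and 5010 ± 2650. Without vehicle 2 the B and plasma cell call was lost (adjusted p = 0.24). In these 3 lists 0 members passed when adjusted over the list alone.

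Interferon response genes had a median log2 fold change of only 0.12, with 15 of 26 above 0 (adjusted p = 0.022; adjusted p = 0.91 with an estimated correlation). *Cxcl9* alone rose when adjusted over the list alone. *Gbp3*, which encodes an interferon-induced GTPase, averaged 190 ± 52.3 and 376 ± 99.0 CPM. The call was lost without vehicle 1 (adjusted p = 0.18) or vehicle 3 (adjusted p = 0.14), and without niclosamide 2 the direction turned (adjusted p = 0.92). Glycolysis and hypoxia genes had a median of 0.35 with 20 of 22 above 0 (adjusted p = 8e-04; adjusted p = 0.91 with an estimated correlation), 0 passing when adjusted over the list alone. *Pdk1*, which restrains pyruvate oxidation, averaged 43.7 ± 2.59 and 74.8 ± 24.5 CPM. Without niclosamide 2 that call was lost (adjusted p = 0.61).

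Smooth muscle genes were lower. The list mean was 7.90 log2 CPM ± 0.19 with vehicle and 6.85 ± 0.85 with niclosamide, without overlap, and 15 of 19 members were below 0 with a median log2 fold change of -1.0 (adjusted p = 2.9e-11; adjusted p = 0.69 with an estimated correlation). *Myh11* averaged 1090 ± 145 and 420 ± 270 CPM (267 without niclosamide 3), *Tagln* 1460 ± 367 and 576 ± 272, *Lmod1* 102 ± 17.4 and 42.7 ± 21.6 and *Pgm5* 318 ± 57.4 and 164 ± 52.9. When adjusted over the list alone 0 members passed. The 4 members above 0 were *Hspb6*, *Casq2*, *Ldb3* and *Synm*, which are also expressed in striated muscle, and which were highest in niclosamide 1 and lowest in niclosamide 2. The skeletal muscle list showed the same extremes, with a mean of 10.71 in niclosamide 1 and 5.58 in niclosamide 2.

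Extracellular matrix genes had a median log2 fold change of -0.39 with 27 of 30 below 0 (adjusted p = 3e-08; adjusted p = 0.49 with an estimated correlation), and list means of 9.38 ± 0.10 and 8.93 ± 0.20 without overlap. *Eln*, the elastin gene, fell when adjusted over the list alone, from 300 ± 51.7 to 110 ± 26.7 CPM, and was the only member to do so; *Col12a1* averaged 705 ± 49.4 and 403 ± 111 CPM and *Col5a1* 556 ± 60.5 and 389 ± 29.2. Matrix remodelling enzymes had a median of -0.23 with 17 of 26 below 0 (adjusted p = 0.002; adjusted p = 0.91 with an estimated correlation). The aggrecanase gene *Adamts5* (64.3 ± 0.697 and 41.2 ± 1.12 CPM) and *Mmp9* (81.5 ± 21.7 and 28.6 ± 9.03 CPM) fell when adjusted over the list alone. That list call was lost without vehicle 1 (adjusted p = 0.18) or niclosamide 3 (adjusted p = 0.28).

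Wnt/beta-catenin target genes had list means of 4.10 ± 0.14 and 3.59 ± 0.21 without overlap and were called lower (adjusted p = 9.9e-05; adjusted p = 0.49 with an estimated correlation), although the median log2 fold change was -0.19 and 8 of 21 members were above 0. *Nkd1* and *Tnfrsf19* (54.7 ± 5.96 and 28.8 ± 3.66 CPM) fell when adjusted over the list alone. *Lgr6* averaged 34.0 ± 24.9 and 6.83 ± 4.44 CPM, where the vehicle mean was 19.7 without vehicle 2 and the niclosamide mean 4.35 without niclosamide 2, and *Notum*, a secreted Wnt deacylase gene, 2.71 ± 0.89 and 1.14 ± 0.496.

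Neutrophil genes had a median log2 fold change of -1.17 with 12 of 16 below 0 (adjusted p = 4.9e-06; adjusted p = 0.70 with an estimated correlation), and the list means of 4.04 ± 0.73 and 3.63 ± 0.63 overlapped. The receptor gene *Cxcr2* averaged 55.9 ± 16.4 and 14.3 ± 7.74 CPM, *Trem1* 21.5 ± 6.04 and 7.06 ± 2.21, *Il1r2* 36.9 ± 8.00 and 13.8 ± 4.37, and 5 members fell when adjusted over the list alone. *Mmp9* was among the 5 and also belongs to the matrix remodelling enzymes, so those 2 list results share a leading gene. The 4 members above 0 were *Mmp8* and the granule protein genes *Ngp*, *Camp* and *Mpo*. Of these, 2 had an unadjusted edgeR p under 0.05, and 0 passed when adjusted over the list alone.

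Estrogen-responsive uterine genes had a median log2 fold change of -0.46 with 15 of 20 below 0 (adjusted p = 5.6e-05; adjusted p = 0.70 with an estimated correlation). Their means overlapped, since niclosamide 1 and 3 had 5.45 and 5.76 log2 CPM and niclosamide 2 had 7.16, against 6.79 to 7.09 with vehicle. *Greb1* averaged 39.8 ± 19 and 16.5 ± 4.95 CPM and *Sprr2b* 179 ± 35.6 and 34.8 ± 26.7. Uterine epithelium markers followed the same libraries, with 4.62, 7.08 and 5.42 in niclosamide 1 to 3 against 5.96 to 6.85 with vehicle, and a median log2 fold change of -0.29 with 21 of 23 below 0 (adjusted p = 0.0014; adjusted p = 0.91 with an estimated correlation). The epithelial call was lost without vehicle 1 (adjusted p = 0.10), niclosamide 1 (adjusted p = 0.77) or niclosamide 3 (adjusted p = 0.057). Genes of the integrated stress response had a median of -0.17 with 18 of 25 below 0 (adjusted p = 0.035; adjusted p = 0.91 with an estimated correlation). *Atf5* averaged 97.4 ± 7.95 and 72.4 ± 0.824 CPM. Their call was lost without vehicle 1 (adjusted p = 0.30), niclosamide 1 (adjusted p = 0.079) or niclosamide 3 (adjusted p = 0.29). In these 3 lists 0 members passed when adjusted over the list alone.

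**Figure D2:**
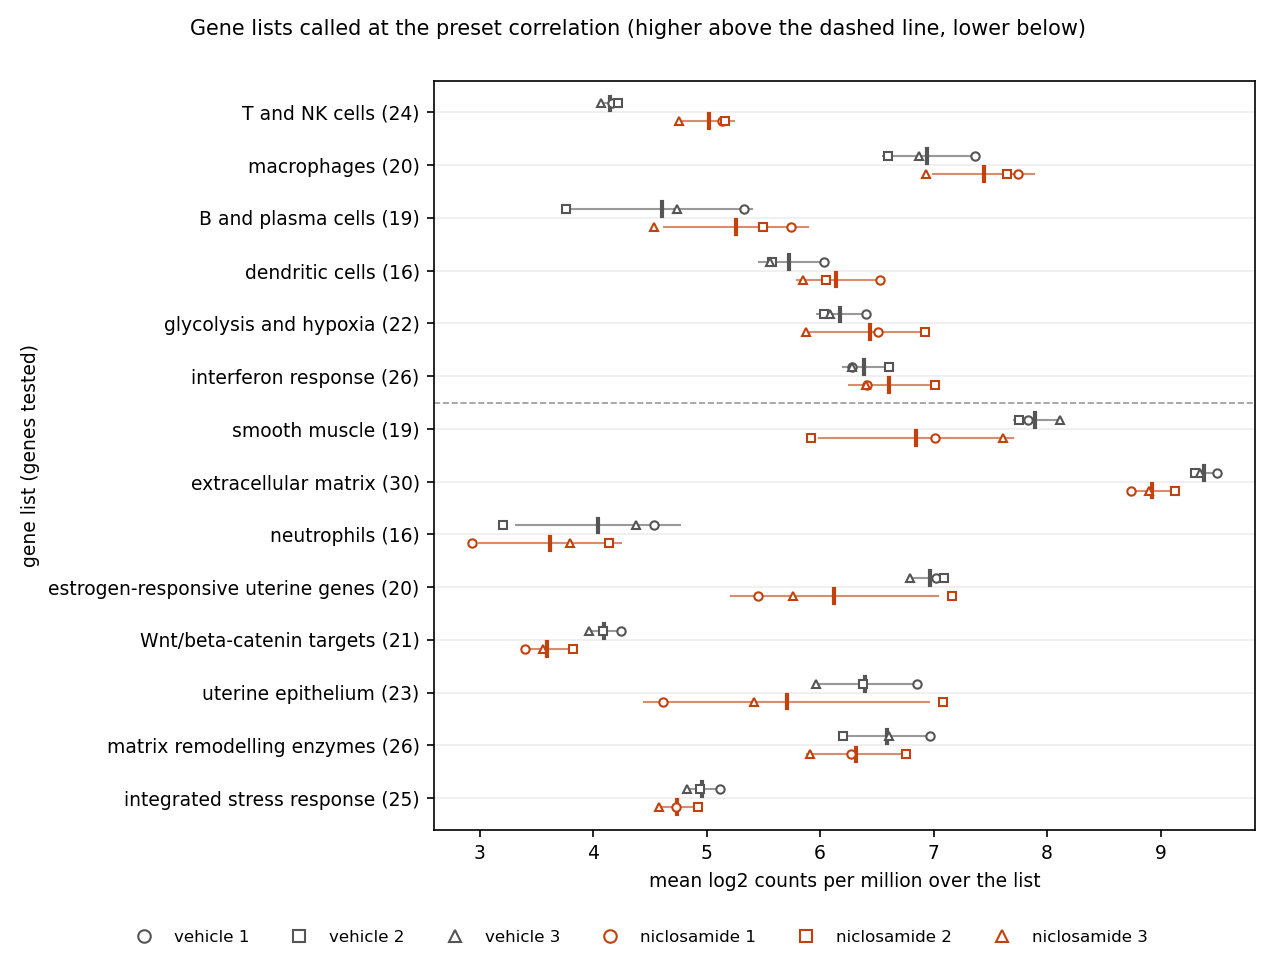
Mean log2 CPM of each gene list called by camera at the preset correlation; each symbol is 1 library, the thick bar is the mean of 3 libraries and the thin line is 1 SD. The groups do not overlap for T and NK cells (4.15 against 5.02), smooth muscle (7.90 against 6.85), extracellular matrix (9.38 against 8.93) and Wnt/beta-catenin targets (4.10 against 3.59), and no list was called with an estimated correlation.

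The niclosamide libraries differed from one another more than the vehicle libraries did, and in tissue markers. Skeletal muscle genes had means of 7.80, 9.08 and 9.16 log2 CPM in vehicle 1 to 3 and 10.71, 5.58 and 9.07 in niclosamide 1 to 3. Their median log2 fold change was 0.74 while the difference of list means was -0.23 (camera adjusted p = 0.58). The skeletal muscle list was called higher without niclosamide 2 (adjusted p = 8.7e-12) and lower without niclosamide 1 (adjusted p = 2.9e-05), and it turned without vehicle 1 (0.56). Adipocyte genes had 4.82, 4.32 and 3.38 with vehicle and 5.92, 1.74 and 3.28 with niclosamide; the median fold change was 0.29, the difference of means -0.53 and the test direction downward (adjusted p = 0.70). The list of adipocytes was called lower without niclosamide 1 (adjusted p = 5e-10) and higher without niclosamide 2 (adjusted p = 0.041), and it turned without vehicle 1 (0.51) or niclosamide 3 (0.69). Progesterone-responsive uterine genes had 3.25, 3.39 and 5.69 in niclosamide 1 to 3 against 3.67 to 3.83 with vehicle (median 0.15, adjusted p = 0.33), and the progesterone-responsive uterine genes were called lower without niclosamide 3 (adjusted p = 0.00099) and higher without niclosamide 1 (adjusted p = 0.00064) or niclosamide 2 (adjusted p = 0.020). Markers of uterine stroma had a median of 0.02, a difference of means of -0.25 and a downward test direction (adjusted p = 0.42); they were called lower without niclosamide 3 (adjusted p = 0.00021) and turned without niclosamide 1 (0.71). The list for steroid synthesis and metabolism had a median of -0.07, a mean log2 fold change of 0.03 and a downward test direction (adjusted p = 0.45), which turned without niclosamide 1 (0.77). Genes of proliferation had a median of 0.24 with 31 of 36 above 0 (adjusted p = 0.074). They turned without vehicle 3 (0.64) or niclosamide 3 (0.91), and were called higher without vehicle 1 (adjusted p = 0.011), vehicle 2 (adjusted p = 0.00035) or niclosamide 1 (adjusted p = 6.4e-17). The calls with a library left out use the preset correlation. Estimated correlations were 0.97 for skeletal muscle, 0.80 for adipocyte and 0.92 for proliferation genes. With these, camera adjusted p over all libraries was 0.95, 0.95 and 0.91. The first principal component of log2 CPM (38% of the variance) had niclosamide 1 and niclosamide 2 at its opposite ends, with the vehicle libraries between them.

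**Figure D3:**
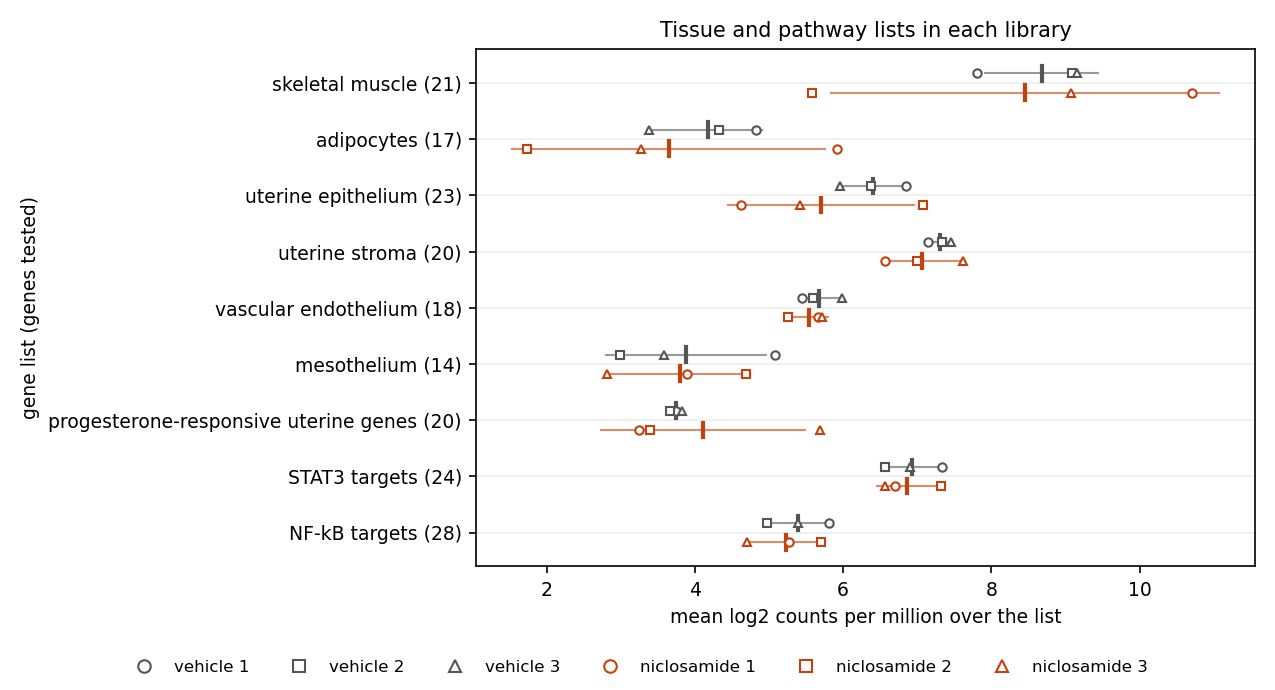
Mean log2 CPM of tissue and pathway lists that were mostly not called; each symbol is 1 library, the thick bar is the mean of 3 libraries and the thin line is 1 SD. Skeletal muscle genes range from 5.58 in niclosamide 2 to 10.71 in niclosamide 1, progesterone-responsive genes reach 5.69 in niclosamide 3, and STAT3 and NF-kB target lists overlap between the groups.

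The 32 lists that were not called had camera adjusted p values between 0.074 and 0.96, and the group means overlapped in 31 of them. The exception was eosinophils (6 genes tested, list means of 2.50 ± 0.24 and 2.81 ± 0.19, adjusted p = 0.42), whose members went both ways: adjusted over the list alone, *Prg2* rose and *Siglecf* fell. The list of cytokines and chemokines had a median log2 fold change of -0.04 (adjusted p = 0.73), and *Cxcl9* alone of its 45 tested members rose when adjusted over the list alone. That list was called lower without vehicle 2 (adjusted p = 0.019) or niclosamide 2 (adjusted p = 0.031) and higher without vehicle 1 (adjusted p = 0.030), and it turned without niclosamide 3 (0.19). Among the lists fixed for RNA quality, immediate early genes (median -0.16, adjusted p = 0.45), heat shock genes (-0.05, adjusted p = 0.63), replication-dependent histones (0.00, adjusted p = 0.96) and cytosolic ribosomal proteins (0.11, adjusted p = 0.16) gave no call. Without vehicle 1 the immediate early genes were called higher (adjusted p = 0.0077) and without vehicle 2 lower (adjusted p = 0.0018), and they turned without niclosamide 3 (0.88). The cytosolic ribosomal proteins were called higher without vehicle 1 (adjusted p = 0.0054) or niclosamide 1 (adjusted p = 3.5e-06) and turned without vehicle 2 (0.96) or niclosamide 3 (0.86). The heat shock list turned without vehicle 1 (0.47) or niclosamide 1 (0.63), and the replication-dependent histones turned without vehicle 2 (0.86), vehicle 3 (0.74), niclosamide 1 (0.79) or niclosamide 3 (0.78). The exocrine pancreas list had fewer than 5 tested members and the mitochondrial genome list had 0 members among the counted symbols, so neither was tested.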

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

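The skeletal muscle covariate was chosen only after the data were seen. The count of genes changed was 0 by edgeR under RLE and upper quartile scaling, the stricter filter, adjusted p under 0.10, the fold change minimum, the muscle covariate and each left-out library, and 0 by limma-voom with and without quality weights. DESeq2 called 178 genes changed, 75 higher and 103 lower, of 17670 given an adjusted p. Without a filter on low counts, 1 gene changed and 1 was lower (Slc24a3). The replicate block gave 0 genes and 14 lists. The labels do not say that replicate numbers pair the samples. Deviations from the group means correlated at -0.08, -0.09 and 0.27 for numbers 1, 2 and 3. Vehicle 1 correlated best with niclosamide 2 (0.36), whereas vehicle 3 and niclosamide 3 correlated best with each other. With 3 libraries per group, these correlations cannot exclude a shared day or litter. Gene lists called numbered 14 under both scalings and the stricter filter, 18 with the muscle covariate, 16 to 23 leaving out one library (23 without vehicle 1 and without niclosamide 2), 0 with an estimated correlation and 0 by fry. No scaling moved the median log2 fold change of all genes by 0.1. Depth limits genes such as Esr2, with 3 to 50 counts per library.

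Over all alternatives, gene lists had 468 values on the same side of the threshold, 43 newly past it, 40 no longer past it and 47 of the opposite direction. The cause of changes in direction was not tested beyond the smaller number of samples, and the list p values use the preset correlation. Leaving out one library turned the direction of the following lists and genes at least once. The camera adjusted p then ranged from 0.0092 to 0.92 for STAT3 targets, 0.0051 to 0.78 for NF-kB targets, 0.019 to 0.77 for cytokines and chemokines, 0.00019 to 0.92 for interferon response, 0.00014 to 0.93 for complement, 6.4e-17 to 0.92 for proliferation, 0.0015 to 0.81 for oxidative phosphorylation, nuclear, 0.026 to 0.80 for ER chaperones, 2.1e-06 to 0.86 for cholesterol synthesis, 0.0024 to 0.71 for fatty acid oxidation, 0.00064 to 0.54 for progesterone-responsive uterine genes, 0.18 to 0.77 for steroid synthesis and metabolism, 0.17 to 0.92 for prostaglandin pathway, 0.00021 to 0.71 for uterine stroma, 0.0072 to 0.99 for vascular endothelium, 0.0097 to 0.92 for large peritoneal macrophages, 0.0077 to 0.96 for mast cells, 5e-10 to 0.81 for adipocytes, 0.017 to 0.71 for mesothelium, 8.7e-12 to 0.88 for skeletal muscle, 0.0018 to 0.88 for immediate early genes, 0.17 to 0.63 for heat shock, 0.42 to 0.86 for replication-dependent histones and 3.5e-06 to 0.96 for cytosolic ribosomal proteins. The log2 fold change ranged from -0.24 to 0.03 for Stat3, -0.05 to 0.19 for Nfkb1, -0.29 to 0.03 for Rela, -1.34 to 1.21 for Il6, -0.21 to 0.29 for Tnf and -1.02 to 0.08 for Ptgs2. The body weight difference ranged from -0.69 to 1.16 g.

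Other settings turned the direction of NF-kB targets (adjusted p = 0.67 with the skeletal muscle covariate, 1 by fry), of skeletal muscle (0.72) and replication-dependent histones (0.99) under the replicate block, of Il6 (log2 fold change 0.06 by limma-voom, 0.35 with quality weights) and of Tnf (0.01 with RLE, 0.00 by DESeq2). At the preset correlation, the called lists that kept their direction and their call without each library in turn were T and NK cells, smooth muscle, extracellular matrix, macrophages, neutrophils, estrogen-responsive genes, Wnt/beta-catenin targets and dendritic cells. None of them kept its call with an estimated correlation or by fry.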

Other observations

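The splits of the edgeR calls, the lymphoid tissue covariate, the comparison of T and NK genes with other cell types, the comparison of smooth muscle with stroma and endothelium, the count of genes high in a single library and the look at structural RNAs were tests chosen only after the results were seen.

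Some genes chosen after their values were seen had higher means with niclosamide without passing the threshold. The cytotoxic protease gene *Gzmb* had 5.76, 11.8 and 5.94 CPM in vehicle 1 to 3 and 20.1, 72.3 and 20.4 in niclosamide 1 to 3, and *Prf1*, the perforin gene, had 7.55, 8.51 and 4.12 against 21.5, 37.6 and 12. Both belong to the T and NK cell list. *Ighg2c*, the constant region gene of an IgG subclass, had 229, 122 and 52.9 against 2110, 2710 and 302 CPM. In other genes the groups overlapped, because niclosamide 3 lay within the vehicle range. *Ifng*, the interferon-gamma gene, had 5.29, 4.42 and 2.14 CPM with vehicle and 18.4, 29.4 and 5.16 with niclosamide, *Cd274*, which encodes the checkpoint ligand PD-L1, 88.1, 70.2 and 56.1 against 214, 217 and 67.3, and *Ido1*, a tryptophan-degrading enzyme gene, 16.3, 3.1 and 0.974 against 41.6, 124 and 10.1. Adjusted p values by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.623 for *Ifng*, 0.602 for *Gzmb*, 0.594 for *Prf1*, 0.675 for *Cd274*, 0.719 for *Ido1* and 0.594 for *Ighg2c*. DESeq2 called 3 of the 6, with adjusted p values of 0.017 for *Gzmb*, 0.026 for *Prf1* and 8e-04 for *Ighg2c*.

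Niclosamide 3 had 17 genes at 10 CPM or more that were at least 8-fold above each of the other 5 libraries. They included *S100g* (177 CPM), *Calb1* (146), *Lrp2* (119), *Cyp26a1* (111), *Sult1d1* (108), *Guca2b* (38.8), *Ihh* (29.8) and *Il13ra2* (29.4), and 4 of the 17 (*Lrp2*, *Cyp26a1*, *Ihh* and *Il13ra2*) belong to the progesterone-responsive list. *Cyp26a1* was 48.1-fold and *Ihh* 63.2-fold above the next library. In niclosamide 1, 15 genes met the same condition, nearly all immunoglobulin segments, against 1 to 4 genes in each other library.

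The group comparison was set against the other ways of parting the 6 libraries into 3 and 3. All 10 of the 10 splits gave as many edgeR calls as the real one, since every split gave 0. By DESeq2 3 of the 10 splits gave as many calls, with 178 for the real split and 609 for the highest other, which set vehicle 1, niclosamide 1 and niclosamide 2 against the rest. By camera 9 of the 10 splits gave as many called lists, with 14 for the real split and 30 for the highest other. Since 10 splits cannot give a share under 0.05, they do not decide whether chance is involved; the 1 split with 609 DESeq2 calls, several times the real number, points to a structure of the samples that does not follow the groups. The real split gave the smallest camera p of all splits in 4 of the 46 lists (8.7%, where chance gives 10%), all 4 among the called ones: T and NK cells (next 6e-08), smooth muscle (next 4.3e-10), extracellular matrix (next 3.1e-05) and Wnt/beta-catenin targets (next 0.008).

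T and NK cell genes were higher in every niclosamide library than in any vehicle library as a list mean. A lower share of smooth muscle and matrix-producing cells would raise the markers of all other cell types alike. A rise shared by all 5 of the other cell types compared here is argued against. T and NK genes exceeded the mean of 5 other cell type lists by 0.99 log2 more with niclosamide than with vehicle, without overlap. Those lists did not move alike. Their means differed by 0.49 for macrophages, 0.12 for mast cells, -0.14 for endothelium, -0.42 for neutrophils and -0.69 for uterine epithelium. The lists that fell enlarge the 0.99, so a rise shared with macrophages is not excluded by this test. B and plasma cell genes (difference of list means 0.65) and dendritic cell genes (0.42) also rose but were not among the 5 lists. A rise shared with these leukocytes is not excluded either. Attached lymphoid tissue stays open. A list of 14 genes of B cell follicles, naive T cells and venules (7 also in lists fixed earlier) had a median log2 fold change of 0.01. The median was 1.05 for 17 cytotoxic lymphocyte genes (13 also in such lists). *Ccl21a*, the most abundant gene of the lymphoid list, averaged 121 CPM with vehicle and 118 with niclosamide. However, the cytotoxic minus lymphoid difference, 1.02 log2 higher with niclosamide, overlapped at vehicle 2 (2.09, against 1.48 in niclosamide 1 and 1.96 in niclosamide 3). The test set beforehand required that it not overlap. A linear model with the lymphoid mean as a covariate decides nothing, since the covariate's slope was 0.00 ± 0.17 (SE) and the group difference of the T and NK list was 0.87 with it and without it. A larger or more activated cytotoxic lymphocyte population also stays open as an untested hypothesis, because bulk counts hold neither cell numbers nor activation per cell, and so does a difference in RNA quality or library composition between the groups, in which *Rn7sk* averaged 26.3 CPM with vehicle and 4.26 with niclosamide.

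The smooth muscle list mean was lower in every niclosamide library than in any vehicle library. Dilution by attached skeletal muscle of the recipient's wall would lower stroma and endothelium alike. However, the smooth muscle mean minus that of stroma and endothelium differed by -0.85 log2 between the groups, without overlap. It was 1.54, 1.28 and 1.38 with vehicle and 0.90, -0.20 and 0.94 with niclosamide. The low value of niclosamide 2 decides nothing about dilution. That library had the lowest skeletal muscle mean, and the smooth muscle list also holds genes shared with striated muscle. Less myometrium in the sampled tissue stays open: the share of the list below 0 was 0.79, between the 0.90 set for this explanation and the 0.75 set against it, and the exceptions were genes shared with striated muscle. Less myometrium and lower expression within muscle cells cannot be told apart here, because bulk counts hold no cell numbers, and a difference in RNA quality or library composition was not tested.

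The progesterone-type genes of niclosamide 3 were compared with lists for decidual cells and for ovary. A decidual response of the list as a whole is argued against, since its mean lay -0.30 log2 from the highest other library (niclosamide 2), with *Prl8a2* and *Prl3c1* at 0 counts in every library, although single members were highest in niclosamide 3: its most abundant gene, *Ctla2a*, had 3140 CPM there, 2080 in vehicle 3 and 190 to 396 in the others, *Tdo2*, which DESeq2 called higher with niclosamide (adjusted p = 4.9e-05), had 3.89 against at most 2.07, and *Wnt6* 4.98 against at most 2.35; 3 of its 13 genes also stood in lists fixed earlier. Attached ovarian tissue is argued against as well, at -0.37 log2 from the highest other library (niclosamide 1); *Star*, the most abundant gene of that list, had 11 CPM in niclosamide 3 and 10.7 to 59.5 in the others, and only 3 of its 8 genes were tested. A candidate explanation that was not tested is a difference in progesterone exposure at collection, for which this is the only library.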
